A study of Homo sapiens with 28 samples.

How the data were processed

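Total RNA from human cerebellum, the hindbrain region that holds granule, Purkinje and Bergmann cells, was measured on 28 Affymetrix arrays, 1 array per sample. The sample titles carry an RNA number followed by an S, an asterisk or nothing, and the meaning of these marks is not given in the sources used here. Samples were grouped by that mark into 11 S-marked, 5 asterisk-marked and 12 unmarked arrays, and are named here by group and a replicate number given in deposit order, which pairs no samples. No diagnosis or other condition is given for the marks, and none was assumed. The labels name 26 biosource codes, of which 2 are each named for 2 arrays. Whether each code stands for 1 donor is not stated, so p-values measure only the spread between these samples.

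The deposited values are linear signal intensities per probe set, per the values themselves, with 1 value for each of 54675 probe sets on each array and 0 missing values. The software that made them is not given in the sources used here. After trimming 2% of values at each end, the mean intensity lay between 149.985 and 149.986 on every array, so that the authors' values share 1 scale per array. Between 23.6% and 29.7% of the values of an array lay under a signal of 16. No detection calls were used here, and the number of arrays limits the precision.

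Values were converted to log2(value + 16), so that a difference on this scale understates the change of weakly expressed genes. Array medians on that scale ranged over 0.302, under the limit of 1 set beforehand, so the deposited scaling was kept. Probe sets were kept when their value exceeded the 40th percentile of all values, a signal of 30.5, on at least 5 arrays. Names came from the platform annotation supplied with the data. Of all probe sets, 41091 had 1 gene symbol, 1801 had several, 11721 had none and 62 were control probe sets. Of those with 1 symbol, 41037 matched a reference gene table by gene ID, and 0 symbols needed an update. Probe sets with several symbols or none were not named, which leaves some list members not analysed here. Each gene was represented by its probe set with the highest mean, and genes on the Y chromosome and the X-inactivation transcripts were left out of every step, which left 15799 genes.

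Differences between marks were tested with limma 3.58.1 in R 4.3.3, with lmFit on 3 group means over all 28 arrays, eBayes with a mean-variance trend, and Benjamini-Hochberg adjustment at 0.05. All p-values are two-sided. Named genes are the 12 with the highest and the 12 with the lowest log2 difference among those past the threshold. Where none passed, the 3 smallest p-values in each direction are given as values. In each list up to 4 passing members are named, or else the 2 with the largest difference. The 20 genes with the largest SD and the 3 members of each cell type list with the highest mean are also named. The 24 gene lists, 14 of cell type markers and 10 of processes, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all lists and the 3 comparisons, and again with an estimated correlation. Groups, tests, lists, naming rules and most alternatives were fixed before the data were examined.

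A list score is the mean over its genes of the log2 value minus the gene's mean over all arrays. The RNA quality index is the mean over GAPDH and ACTB of the log2 value of the 3′ control probe set minus that of the 5′ one, and is higher where RNA is shorter. Correlations of scores used Pearson's r and Spearman's rho with 100000 permutations, adjusted over 24 lists or over 10 pairs of scores. Where a score had a gap of over 0.5 between neighbouring arrays, r was taken over the arrays on the larger side, a rule chosen after seeing the data. The spread of each list was set against 10000 random lists of the same size matched on mean expression in 20 bins. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for these steps and the plots.

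Principal components separated arrays by the RNA number in the titles, at 12, and this division was then added to the fits as a block, after the data were seen. Other alternatives were the pseudocount, quantile scaling, centring on medians, other filters, the choice of probe set, the quality index as a covariate, biosource as a random block, array weights, a block on RNA number and leaving out single arrays.

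The fit was tested on simulated data for 15799 genes with real means and spreads, 200 of them changed. For S-marked minus unmarked it recovered 38.8% of genes changed by 0.5 on the log2 scale, 80.6% of those changed by 1 and 100% of those changed by 2. For asterisk-marked minus unmarked the shares were 29.9%, 79.1% and 100%, and for S-marked minus asterisk-marked 20.9%, 71.6% and 100%. False calls numbered 10, 7 and 6. Each gene was drawn independently, so these figures leave out structure shared between genes and may not hold for the real arrays. The list test was run on arrays simulated in this way with the ribosomal protein list shifted, and the correlation test on simulated pairs of known correlation.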

Results

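Gene expression was measured in 28 samples of human cerebellum, 11 S-marked, 5 asterisk-marked and 12 unmarked, with the median array at a signal of 45.7. Signals of different genes come from different probes and give no order between genes. Among granule cell genes, the transcription factors ZIC1, ETV1 and ZIC2 had median signals of 16689, 5080 and 4741. Purkinje cell genes CALB1, PCP4 and ITPR1, which act in calcium binding and calcium release, had median signals of 4327, 3481 and 2746. The interneuron genes PVALB, GAD1 and KIT stood at 5857, 1818 and 1377. NEFH, EOMES and MEIS2, listed for the deep nuclei and unipolar brush cells, stood at 829, 762 and 712.

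The glial genes given are the 3 members of each list with the highest mean. FABP7, SLC1A3 (the glutamate transporter of Bergmann glia) and GFAP had median signals of 5123, 6028 and 2857, and the myelin genes MBP, MOBP and CNP 9032, 848 and 733. OLIG1, PDGFRA and NKX2-2 of oligodendrocyte precursors stood at 594, 222 and 165, and the microglial genes LAPTM5, CX3CR1 and CD14 at 118, 112 and 103. Of the other members of these lists, GPR17 of precursors stood at 38.0 and microglial C1QB and C1QA at 32.3 and 31.2, and microglial TREM2 and AIF1, at 18.6 and 13.2, lay under the filter signal of 30.5. The vessel genes RGS5, ACTA2 and CLDN5 stood at 638, 283 and 188, the fibroblast genes DCN, COL1A2 and COL1A1 at 280, 99.1 and 70.4, and the ventricular genes FOLR1, AQP1 and TTR at 888, 181 and 9.09. HBB, which encodes beta globin, had a median signal of 1867. S100A8 and ALAS2, at 19.3 and 20.3, lay under the filter signal of 30.5. The lymphocyte genes CD8A, CD79A and MS4A1 stood at 49.4, 46.4 and 18.0. Of the forebrain list, NEUROD6 stood at 131 and EMX1 at 26.9.

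Genes differed widely in how far they varied from sample to sample. The median SD over all genes was 0.36 on the log2 scale, and 40 genes had an SD over 1. Astrocyte and Bergmann glia genes and immediate early genes had median SDs of 0.81 and 0.76, where random lists matched on expression had medians of 0.23 and 0.33. Heat shock genes stood at 1.01 against 0.25, but 2 arrays with scores of 3.69 and 2.56 carried that SD, which was 0.27 without them, at the 81.2nd percentile of random lists. Without these 2 arrays astrocyte and immediate early genes stood at 0.79 and 0.54. The array with the score of 3.69 also had the highest RNA quality index, 2.99. In all, 16 of 24 lists had a median SD above the central 95% of matched random lists, 12 without the 2 arrays and 12 with the median absolute deviation. Ribosomal protein genes had a median SD of 0.17 and oxidative phosphorylation genes 0.21, at the 1.13th and 23.9th percentiles of their random lists. Cell type lists differed too, but so did their matched random lists. Granule cell genes stood at 0.30 against 0.21, Purkinje cell genes at 0.41 against 0.23 and oligodendrocyte genes at 0.51 against 0.28. Precursor genes stood at 0.66 against 0.34 and microglial genes at 0.70 against 0.47. Inhibitory interneuron genes, at 0.32 against 0.30, lay at the 71st percentile of their random lists.

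**Figure D1:**
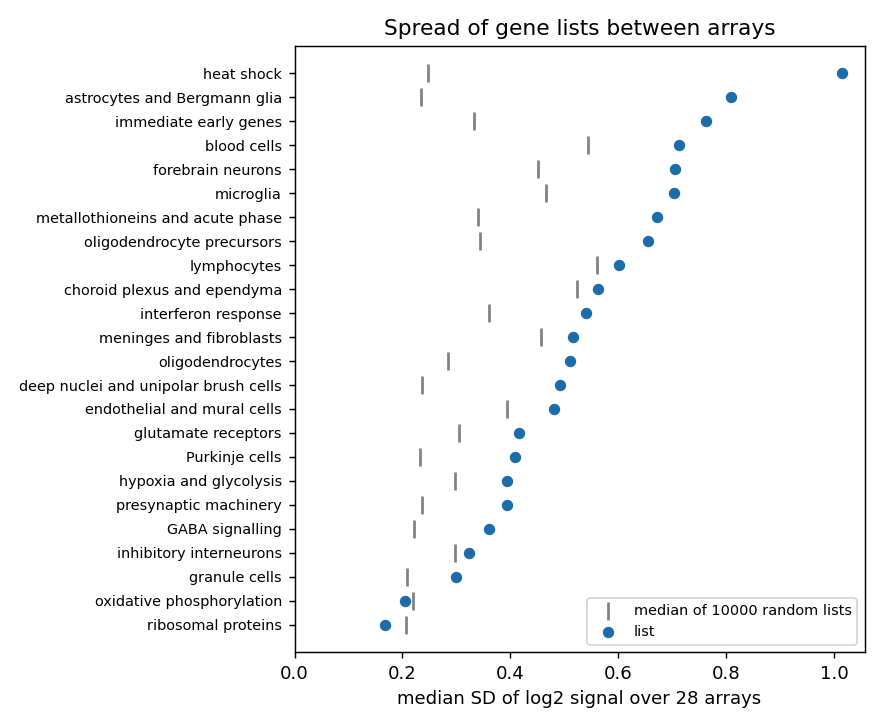
Median SD of log2 signal over 28 arrays for 24 gene lists (points, horizontal axis in log2 units) and for matched random lists (grey ticks). Heat shock genes lie farthest right at 1.01, a value carried by 2 arrays (0.27 without them), and ribosomal protein genes farthest left at 0.17.

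The 20 most variable genes included 10 members of the fixed lists. GSTT1, a glutathione transferase, had an SD of 1.83 and ran from a signal of 2.23 to 621. PSPH, which makes serine, had an SD of 1.75 and ran from 20.4 to 782. The inducible chaperones HSPA6, DNAJB1 and HSPB1 reached 5927, 20820 and 9314 from medians of 32.6, 484 and 285. Among astrocyte genes, SLC1A3 ranged from 332 to 8372, the gap junction gene GJA1 from 179 to 4768 and the water channel gene AQP4 from 166 to 4033. GJB6, LCAT, KCNJ16 and APOE had SDs of 1.26, 1.16, 1.15 and 1.12. The immediate early genes EGR1 and FOS reached 14078 and 1641 from medians of 772 and 154. SERPINA3, an acute phase protein, reached 1319 from 41.9, and TTR, the transthyretin gene of choroid plexus, reached 588 from 9.09. The remaining genes were LINC01561, LOC100505874, OTX2 and C6orf141, with SDs of 1.43, 1.33, 1.12 and 1.12. With the median absolute deviation in place of the SD 5 of these 20 genes were among the 20 most variable, and with a pseudocount of 1 there were 9.

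**Figure D2:**
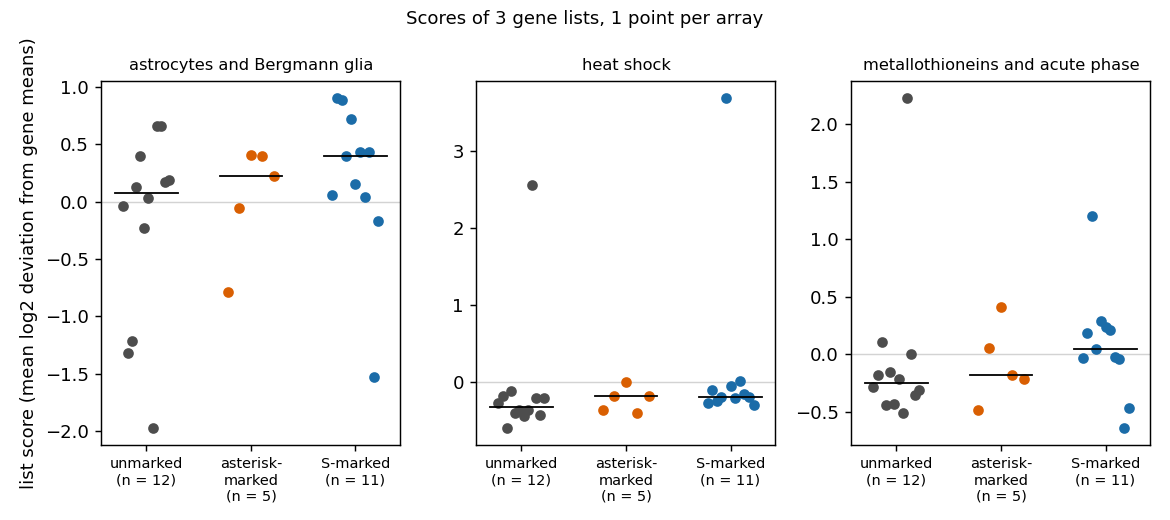
Scores of 3 gene lists on each array by mark (vertical axis, mean log2 deviation from each gene's mean; points are arrays, black lines group medians; 12 unmarked, 5 asterisk-marked, 11 S-marked). In the heat shock panel 2 arrays stand at 2.56 and 3.69 and all others at 0.02 or lower, and in the astrocyte panel 5 arrays lie at −0.79 or lower.

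Between S-marked and unmarked cerebellum, 52 of 15799 genes differed, 20 higher and 32 lower in the S-marked arrays. That balance turned in other fits, with 621 higher and 317 lower with array weights, 70 and 41 without arrays of shared biosource, and 235 and 133 without unmarked replicate 2. ZNF423, a zinc finger factor needed in cerebellar development, was 9.80 ± 0.21 (SD, n = 11) in S-marked and 8.93 ± 0.33 (SD, n = 12) in unmarked arrays. This log2 difference was 0.87 ± 0.12 (SE, limma adjusted p = 0.000618). SLC4A2, an anion exchanger, was higher by 1.25 ± 0.24 (limma adjusted p = 0.0291) and KLF16, a zinc finger factor, by 1.24 ± 0.24. SNPH, which anchors mitochondria in axons, was higher by 0.92, PLTP (phospholipid transfer) by 0.90 and HUWE1 (a ubiquitin ligase) by 0.90. Other genes higher in S-marked arrays were TNK2 (0.71), IGSF9B, a cell adhesion gene of inhibitory synapses (0.70), LOC729732 (0.67), NOTCH3 of vessel mural cells (0.66), PLXNA1, a semaphorin receptor (0.66), and CRELD2 of the endoplasmic reticulum (0.65). The log2 difference was −1.17 ± 0.24 for LINC01535 (limma adjusted p = 0.0323), −1.12 ± 0.24 for BCL6B, a transcriptional repressor, and −0.91 for SLC3A1, an amino acid transporter subunit. Lower by smaller amounts were GPR137C (−0.69), OTUD6B-AS1 (−0.67), RBM4, a splicing factor (−0.65), LOC102724851 (−0.64), CTBS (−0.63), WDR17 (−0.59), ABCA11P (−0.59), PCMTD2 (−0.56) and SKIC3 of the RNA-degrading Ski complex (−0.53). In each of these genes at least 10 of the 11 S-marked arrays lay beyond the unmarked median. Genes chosen by their differences in the same arrays tend to show this, so it adds no separate support.

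Several of these sizes depended on the probe set or on the pseudocount. The 4 other probe sets of HUWE1 ran from −0.24 to 0.23, 2 of them opposite to the named one, and the mean of its probe sets gave 0.20 (limma adjusted p = 0.287). Another probe set of LOC729732 stood at −0.01 and one of PCMTD2 at 0.18, and BCL6B stood at −0.41 with the mean of its probe sets (limma adjusted p = 0.158). With that mean 13 of the 24 named genes did not pass. Among them PLTP, SLC3A1, GPR137C and RBM4 had no other probe set and unchanged differences. Their limma adjusted p rose to between 0.0539 and 0.0571, so these losses say nothing on the choice of probe set. SLC4A2, KLF16, LINC01535 and BCL6B had a lower group under the filter signal of 30.5, at 16.4, 16.2, 12.8 and 19.1. Their differences were 2.10, 1.94, −2.08 and −1.86 with a pseudocount of 1 and 0.61, 0.62, −0.56 and −0.56 with 64, where HUWE1 stood at 0.89.

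**Figure D3:**
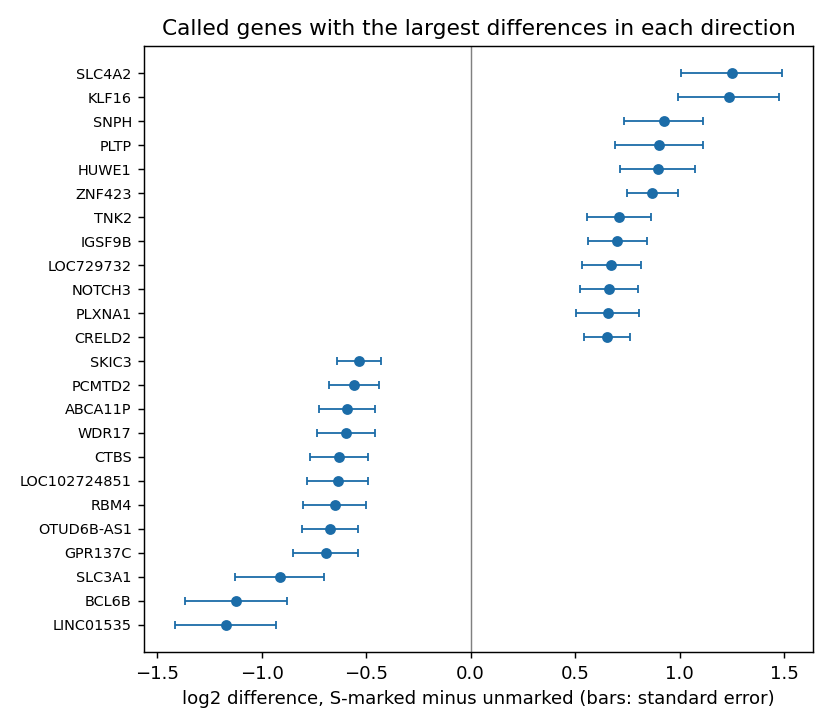
Log2 difference between 11 S-marked and 12 unmarked arrays for the 12 highest and 12 lowest of the 52 genes past the threshold (points, with standard error bars). The values run from −1.17 for LINC01535 to 1.25 for SLC4A2 with a pseudocount of 16; those 2 stand at −0.56 and 0.61 with 64.

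The S-marked and unmarked arrays were unevenly spread over the RNA numbers in the titles. Of the 15 arrays with a number under 12, 10 were S-marked, 3 unmarked and 2 asterisk-marked, and 1 of the 13 arrays with a number of 12 or over was S-marked. With this division as a block, 0 of 15799 genes passed in limma (smallest adjusted p = 0.356) and 957 had an unadjusted p under 0.05. The median size of the 52 differences was then 0.32 in place of 0.56, with all 52 in the same direction and 41 at an unadjusted p under 0.05. These genes were chosen by their differences in the same arrays, so their kept direction and small p-values are no separate support for the mark. Among arrays with a number under 12 alone, 10 S-marked against 3 unmarked, 0 genes passed in limma, 1249 had an unadjusted p under 0.05 and the median was 0.39. With arrays centred on their medians 7 genes passed, 5 higher and 2 lower. Leaving out 1 array gave between 2 genes, without unmarked replicate 6, 7 or 11 or S-marked replicate 3, and 446, 237 higher and 209 lower, without S-marked replicate 11.

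None of the 24 lists passed between S-marked and unmarked arrays. The presynaptic list came nearest (camera adjusted p = 0.0541, and adjusted p = 0.939 with an estimated correlation), with 11 of its 15 measured members at positive differences. SYP, of synaptic vesicles, had a log2 difference of 0.59 ± 0.24 and VAMP2, of vesicle fusion, 0.51 ± 0.15, and neither passed over all genes. VAMP2 was the 1 member that passed when adjusted over the list alone. In GABA signalling, 5 of 9 measured members passed adjusted over the list alone, 4 higher and ABAT lower (−0.20 ± 0.07), and 0 over all genes. The same 5 differed in the same direction between RNA numbers under 12 and of 12 or over (limma adjusted p from 4.235e-08 for GABBR1 to 0.0307 for GABRB2). Mark and RNA number overlap and the division at 12 came from the same data, so this agreement was partly built in and is no separate support. Of all tested genes, 21.9% differed between the RNA number sets. With that division as a block, 0 members of any list passed in limma adjusted over the list alone. The GABA genes with the largest differences were the receptor genes GABBR1 (0.47 ± 0.12, limma adjusted p = 0.0601) and GABRB2 (0.45 ± 0.11). Of the immediate early genes, JUNB and FOS stood at 0.64 ± 0.30 and 0.57 ± 0.41, and JUN, at 0.36 ± 0.10, was the 1 of 9 that passed adjusted over the list alone. Of 12 vessel genes NOTCH3 was the 1 that passed, over all genes and adjusted over the list alone. Glutamate receptor genes GRIA1 (0.51 ± 0.32) and GRM4 (0.44 ± 0.14) did not pass.

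Astrocyte and Bergmann glia genes gave a median log2 difference of 0.41 between S-marked and unmarked arrays, with SLC1A3 at 0.77 ± 0.50 and SOX9 at 0.71 ± 0.31, and 0 of 12 passed. Of the 5 arrays far below the others in this score, 3 were unmarked, 1 S-marked and 1 asterisk-marked. In granule cells GABRD stood at 0.36 ± 0.14 and GABRA6 at −0.34 ± 0.22, in Purkinje cells PCP2 at 0.32 ± 0.15 and HOMER3 at 0.22 ± 0.11. PAX2 and SLC6A5 of interneurons stood at 0.32 ± 0.13 and 0.23 ± 0.17, and EOMES and NEFH at 0.29 ± 0.19 and 0.28 ± 0.18. MAG and OPALIN of oligodendrocytes stood at 0.47 ± 0.22 and −0.41 ± 0.20, and NKX2-2 and OLIG1 of precursors stood at 0.67 ± 0.23 and 0.35 ± 0.19, NKX2-2 passing adjusted over the list alone. Microglial ITGAM stood at −0.39 ± 0.20 and C1QC at 0.31 ± 0.32, blood HBB at 0.45 ± 0.32 and ALAS2 at −0.14 ± 0.22, and choroid TTR at 0.83 ± 0.45 and CLIC6 at 0.39 ± 0.23. For fibroblasts COL1A2 and OGN were at 0.47 ± 0.19 and 0.29 ± 0.26, for lymphocytes CD79A and CD8A at 0.22 ± 0.25 and −0.19 ± 0.21, and for forebrain neurons NEUROD6 and EMX1 at −0.20 ± 0.29 and −0.09 ± 0.27. Among process lists, HSPB1 and DNAJB1 of heat shock stood at 0.63 ± 0.45 and 0.57 ± 0.45. The S-marked group holds replicate 5, with a heat shock score of 3.69 and an RNA quality index of 2.99. MT1M and GADD45B stood at 0.43 ± 0.30 and 0.43 ± 0.22, and IFIT3 and ISG15 at 0.50 ± 0.20 and 0.41 ± 0.20. VEGFA and PFKFB4 stood at 0.39 ± 0.18 and −0.36 ± 0.18, COX5A and UQCRC1 at 0.29 ± 0.13 and 0.22 ± 0.11, and RPL30 and RPL3 at 0.17 ± 0.12 and −0.13 ± 0.07.

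Between asterisk-marked and unmarked arrays, interferon response genes were higher as a list and ribosomal protein genes lower with the preset correlation, but neither list passed with an estimated correlation (adjusted p = 0.939 for both), and each call was lost without certain single arrays. Of 11 measured interferon genes, 9 had positive differences (camera adjusted p = 0.00899), led by the antiviral genes IFIT3 at 0.73 ± 0.25 and OAS1 at 0.60 ± 0.28. All 12 measured ribosomal protein genes had negative differences with a median of −0.09 (camera adjusted p = 0.0234), with RPL8 at −0.19 ± 0.13 and RPS6 at −0.15 ± 0.08. The interferon score averaged 0.54 in the 2 asterisk-marked arrays with RNA numbers under 12, replicates 2 and 3, and −0.19 in the 3 unmarked arrays of that set. On the same arrays the microglia score averaged 0.53 and −0.17, and unmarked replicates 2 and 3 of that set were 2 of the 5 arrays with the lowest astrocyte scores. In numbers of 12 or over the interferon score averaged −0.10 in the 3 asterisk-marked and −0.10 in the 9 unmarked arrays. The list's mean difference was 0.73 within numbers under 12 (camera adjusted p = 6.375e-06), 0.0014 within 12 or over (camera adjusted p = 0.853) and 0.26 with the division as a block (camera adjusted p = 0.0109). Without asterisk-marked replicate 2 or 3 the camera adjusted p was 0.198 or 0.0577. The ribosomal list passed within numbers under 12 and with the block (camera adjusted p = 0.00895 and 0.00103). It was lost within 12 or over (camera adjusted p = 0.0826), without the 4 arrays of shared biosource (0.327), without unmarked replicate 1, 2 or 3 (0.0512, 0.186 and 0.0897) and without asterisk-marked replicate 1 or 5 (0.0814 and 0.173). Unmarked replicates 2 and 3, with ribosomal scores of 0.32 and 0.28, and asterisk-marked replicate 1 were among the 5 arrays of lowest astrocyte score. With that score as a covariate the camera adjusted p was 0.068 for the ribosomal and 0.00894 for the interferon list, and with the microglia score 0.0146 for both. No single gene passed over all genes or adjusted over either list alone, with 0 of 15799 called by limma and 424 at an unadjusted p under 0.05. The smallest p-values belonged to ZFP64 (0.38 ± 0.09), OTX1 (0.99 ± 0.27) and HTR1F (1.05 ± 0.29) at positive differences, and to LINC01505 (−0.90 ± 0.24), GHRLOS (−1.02 ± 0.28) and COL21A1 (−1.13 ± 0.32) at negative ones, all with a limma adjusted p of 0.9999. In 4 of these 6 genes, OTX1, HTR1F, LINC01505 and GHRLOS, the lower group lay under a signal of 30.5, so that the size depends on the pseudocount.

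Between S-marked and asterisk-marked arrays 1 gene differed, ZNF423, which was higher in S-marked arrays by 0.96 ± 0.16 (limma adjusted p = 0.0132). It had a mean of 9.80 in the 11 S-marked and 8.85 in the 5 asterisk-marked arrays, and all 11 S-marked arrays lay above the asterisk-marked median. With the RNA number division as a block 0 genes passed (smallest limma adjusted p = 0.169, 611 at an unadjusted p under 0.05), and without asterisk-marked replicate 4 or 5 the adjusted p was 0.265 or 0.232. None of the 24 lists passed, with the presynaptic list at a camera adjusted p of 0.0541 (adjusted p = 0.939 with an estimated correlation). Adjusted over the list alone, 2 of 9 GABA signalling genes and 1 of 9 immediate early genes passed, 0 over all genes, and 0 of either list adjusted over the list alone with the block.

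Scores of oxidative phosphorylation genes and presynaptic genes rose together over the 28 arrays. Pearson's r was 0.59 (permutation p = 0.00061, adjusted p = 0.0061) and Spearman's rho 0.68 (permutation p = 9e-05), and r was 0.72 without the 2 arrays farthest from the median. Without the 4 arrays of shared biosource r was 0.48 and did not pass (24 arrays, permutation p = 0.0152, adjusted p = 0.0762). Both arrays of 1 shared code and 1 array of the other are among the 5 of lowest astrocyte score, so this alternative does not isolate biosource. Within RNA numbers under 12 r was 0.66 (15 arrays, permutation adjusted p = 0.0861) and within 12 or over 0.71 (13 arrays, permutation adjusted p = 0.0227). Metallothionein and acute phase scores rose with the astrocyte score over the 21 arrays on the larger side of the gaps, with r = 0.61 (permutation p = 0.00321, adjusted p = 0.016) and rho = 0.59 (permutation p = 0.00587). Without shared biosource r was 0.63 on that side (20 arrays, permutation p = 0.003, adjusted p = 0.03), but 0.47 over all 24 arrays, which did not pass (permutation p = 0.0345, adjusted p = 0.0831). On the larger side r was 0.58 without the 2 farthest arrays, 0.46 within 11 arrays of RNA number under 12 (permutation adjusted p = 0.305) and 0.89 within 10 arrays of 12 or over (permutation adjusted p = 0.0064). Over the larger side of the gaps none of the other 8 pairs passed by Pearson's r. Among those 8, granule cell with astrocyte scores (r = −0.44) and oligodendrocyte with astrocyte scores (0.43) passed over all 28 arrays. So did heat shock scores with immediate early (0.49) and with metallothionein and acute phase scores (0.55). Each of these had a permutation adjusted p of 0.0476. By rank, metallothionein and acute phase scores rose with the microglia score over 25 arrays, with rho = 0.53 (permutation p = 0.00712, adjusted p = 0.0237), where r was 0.48 (permutation p = 0.0153, adjusted p = 0.051) and 0.36 without the 2 farthest arrays. That r was 0.49 within 13 arrays of RNA number under 12 (permutation adjusted p = 0.219) and 0.62 within 12 arrays of 12 or over (permutation adjusted p = 0.078). Over all 28 arrays the RNA quality index passed with the deep nuclei list (r = 0.68, permutation adjusted p = 0.00168). It also passed with the microglia list (r = −0.58, permutation adjusted p = 0.0078). The index was 2.99 in S-marked replicate 5 and between 0.71 and 1.61 elsewhere. Over the 27 other arrays none of its 24 relations passed by Pearson's r (smallest permutation adjusted p = 0.0725), with r = 0.55 for the deep nuclei list and −0.51 for oligodendrocytes. By rank both passed there, with rho = 0.61 (permutation p = 0.00097, adjusted p = 0.0206) and −0.58 (permutation p = 0.00172, adjusted p = 0.0206). Within RNA numbers under 12, without S-marked replicate 5, r was −0.78 for oligodendrocytes (14 arrays, permutation adjusted p = 0.0247) and 0.60 for the deep nuclei list (permutation adjusted p = 0.156). Within 12 or over, r was −0.24 (13 arrays, permutation adjusted p = 0.808) and 0.52 (permutation adjusted p = 0.381).

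**Figure D4:**
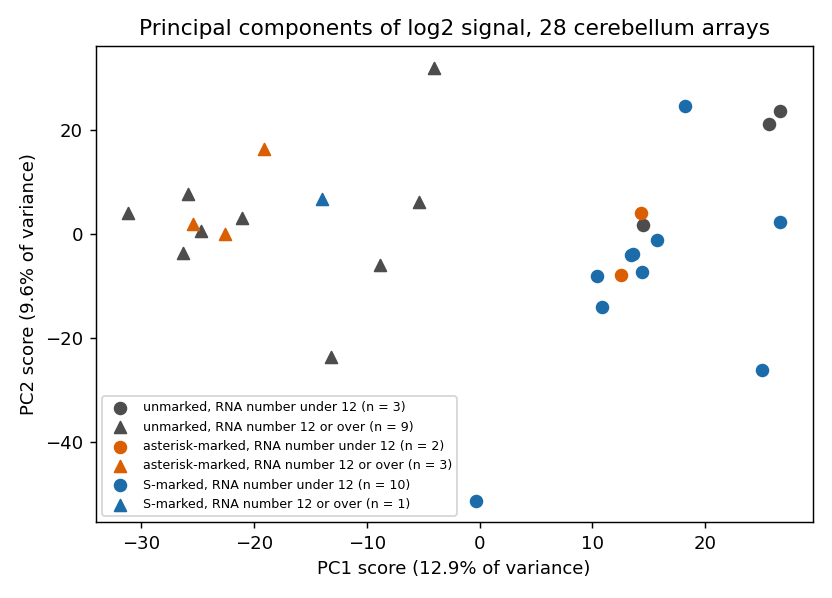
Scores of the first 2 principal components of log2 signal for 28 arrays (PC1 12.95% and PC2 9.60% of variance; colour shows the mark, circles an RNA number under 12 and triangles 12 or over). On PC1, 14 of 15 circles lie above 0 and all 13 triangles below it.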

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

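The test with the division of RNA numbers at 12 as a block and the splits within its sets were chosen after the results were seen. Among the 5 asterisk-marked arrays, the microglia score of replicate 1 was −0.55 and stood apart from the others, which reached 0.54. Its gap to the nearest array was 0.713 of the group's range, just over the critical value of 0.71 for 5 values. It was 1 of 25 scores tested in this group, and chance alone flags about 1 in 20, so a single flag carries little weight.

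For the 52 genes that differed between S-marked and unmarked arrays, 2 of 100 splits of the same sizes, the real one included, called as many. That met the bound set beforehand against chance, but these splits ignore the uneven RNA numbers, so they do not exclude chance. The highest other split called 483, several times the real count, which points to a structure of the samples. Of 100 splits that kept how many arrays of each mark lie in each RNA number set, 45 called at least 52 genes and the highest other called 1304, so chance could not be excluded once the uneven RNA numbers are kept. RNA degradation is argued against, since with the quality index as a covariate the median size of the differences stayed at 93.89%, with all 52 in the same direction and 29 past the threshold. The division of RNA numbers at 12 may account for part or all of the count, and 47 of the 52 genes also differed between the sets in the same direction, where in those splits a median of 49 of the 52 leading genes differed between the sets (36 to 52). With it as a block their median size fell to 58.55% of its value and the median SE went from 0.12 to 0.13, so that the calls ended mostly through smaller differences, and mark and RNA number cannot be told apart for these genes, and a biological difference behind the S mark stays open, as untested.

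For the other comparisons, asterisk-marked minus unmarked called 0 genes in limma (424 at an unadjusted p under 0.05), a count that any split reaches, so that 100 of 100 splits say nothing on chance. The highest other split called 985, which again points to a structure of the samples. For S-marked minus asterisk-marked, 4 of 100 splits called at least the 1 gene seen, with 1 gene in the highest other. That share met the bound set beforehand against chance, but 3 other splits reached the same count of 1 gene. These splits ignore the RNA numbers, so they do not exclude chance. Of 100 splits that kept the marks of each RNA number set, 13 called at least 1 gene and the highest other called 117, so chance could not be excluded with these numbers kept. With the RNA number division as a block the call was lost (0 genes in limma, smallest adjusted p = 0.169, 611 at an unadjusted p under 0.05), as it was without asterisk-marked replicate 4 or 5 (limma adjusted p = 0.265 and 0.232).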

How the results depend on the processing

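Alternatives by the division of RNA numbers at 12, by a gap in scores, by cell type scores as covariates, without S-marked replicate 5 for scores, without the 2 arrays of highest heat shock score for spread, all that leave out an array for the lists, and the fit of the same 8 arrays with no replicate block, were chosen after seeing the data. Between S-marked and asterisk-marked arrays 1 gene was called in every other alternative run, but 0 with the RNA number division as a block, and leaving out single arrays gave 0 to 1, with 0 without asterisk-marked replicate 4 or 5. Asterisk-marked minus unmarked gave 0 in each alternative run. The 52 genes between S-marked and unmarked arrays moved more. The count was 79 with quantile scaling, 7 with medians centred, 33 with no filter and 145 with a stricter one, 27 with the mean of a gene's probe sets, 111 without arrays of shared biosource, 938 with array weights, and 172 for S-marked against all others. It was 0 with the RNA number division as a block and 0 for RNA numbers under 12 alone. With RNA number as a replicate block, over 8 arrays, it was 0, as it was in the same 8 arrays with no replicate block. Those arrays are fewer and balanced for RNA number, and the median size over the 24 named genes was 0.45 in place of 0.68, so the loss is not put down to array number alone. The 4 RNA numbers shared by both marks gave correlations of 0.0017 to 0.21. No reference for arrays of 1 donor was at hand, so these values do not settle whether the numbers pair the arrays. The labels name different biosource codes for the S-marked and the unmarked array of each shared number. Both arrays of 1 shared biosource code and 1 array of the other are among the 5 of lowest astrocyte score. Counts without shared biosource therefore do not isolate biosource. Leaving out single arrays gave 2 to 446 genes. The count was 368, 299 and 200 without unmarked replicates 2, 3 and 4, 128 and 446 without S-marked 5 and 11, 2 without unmarked 6, 7 or 11 or S-marked 3, 3 without S-marked 9, 4 without unmarked 5 or 12 and 10 without unmarked 10. It was 33 without unmarked 9, and 24, 29, 32, 32, 28 and 23 without S-marked 1, 2, 4, 6, 7 and 8. Unmarked 2, 3 and 4 are the 3 unmarked arrays with RNA numbers under 12. S-marked 11 is the 1 S-marked array of 12 or over. Without any of these arrays, mark and RNA number overlap more closely, and the count rose. It also rose without S-marked 5 and, to 72, without S-marked 10, both under 12, so this overlap does not cover every rise. The cause was not tested further.

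Of 2 called lists, counted over the 24 lists and 3 comparisons, 0 remained with an estimated correlation. The count was 4 with the quality index as a covariate, 4 with the astrocyte score as one, 4 without shared biosource, 7 with the RNA number block, 22 for RNA numbers under 12 alone, with 2 asterisk-marked arrays there, and 5 without S-marked replicate 5. Leaving out single arrays gave 1 to 10 lists, with 10 without asterisk-marked 1 or unmarked 9, 5 without asterisk-marked 4 or unmarked 5 or 10, 4 without unmarked 6 or 11 or S-marked 2, 3, 4 or 8, and 1 without asterisk-marked 3 or 5 or unmarked 1. Relations with the quality index numbered 2 over all arrays, with ACTB alone, with a pseudocount of 1, with quantile scaling, within marks and within RNA numbers under 12, 3 without shared biosource, 1 with GAPDH alone, and 0 without the 2 farthest arrays, without S-marked replicate 5, over the larger side of a gap or within RNA numbers of 12 or over. Of 10 pairs 6 passed over all arrays, 2 without the 2 farthest arrays, 2 over the larger side of a gap, 1 without shared biosource (immediate early and heat shock scores), 1 on the larger side of a gap without shared biosource (metallothionein and astrocyte scores) and 0 within RNA numbers under 12. The pair of oligodendrocyte and astrocyte scores turned to −0.0379 over the larger side of a gap and −0.0553 there without shared biosource. The cause was not tested. For the 24 genes named between S-marked and unmarked arrays, 536 of 932 values under alternatives stayed past the threshold in the same direction and 396 did not pass, with 0 reversed. For ZNF423 between S-marked and asterisk-marked arrays 25 of 28 stayed past it. Low signals limit genes near 16, the pseudocount.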

Other observations

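The division by RNA number at 12, the random splits tested against it and the count over 7 genes for shared biosources were chosen after the results were seen. Between arrays with RNA numbers under 12 and those of 12 or over, 3460 of 15799 genes differed in limma, 2120 higher and 1340 lower. NFIX, a transcription factor of granule neurons, was higher under 12 by 1.91 ± 0.15 on the log2 scale (limma adjusted p = 4.802e-11), and DGKZ, a diacylglycerol kinase, by 1.46 ± 0.11. ELN, PRR36, KLF16 and MINK1 were higher by 1.48, 1.42, 1.41 and 1.31, and SLC3A1, EPB41L4A and SOD2 stood at −1.21, −1.03 and −0.88. These genes were chosen after their values were seen, and ELN, PRR36 and KLF16 averaged under the filter signal in arrays of 12 or over, so that their sizes depend on the pseudocount. Of 15 presynaptic genes 8 were higher under 12, among them SYP (1.07 ± 0.14) and VAMP2 (0.78 ± 0.08), a list adjusted p of 0.000327 with the preset correlation and an adjusted p of 0.891 with an estimated one. The same comparison gave 2090 genes with the mark as a term and 1750 among the arrays without the S mark. The threshold of 12 came from the data, so these counts describe these arrays.

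Several causes of this division were weighed. Random splits of the same sizes called at most 817 genes, and 1 of 100 splits, the real one, called 3460, but 12 was chosen where the leading component of the same data parts, so this comparison says nothing on chance. RNA degradation and cell mix are argued against as the whole cause. With the quality index as a covariate 3637 genes passed, 3282 of them among the 3460, and with 5 cell type scores 3360 passed, 1854 higher and 1506 lower, of which 2570 were among the 3460, so that a part through cell mix stays open. A laboratory batch stays open. The control transcripts added at hybridization differed by 0.15 (95% bootstrap interval 0.03 to 0.27, permutation p = 0.0268). Those added before labelling differed by −0.16 (−0.30 to −0.0011, permutation p = 0.0548). Both intervals exclude 0, but the smaller permutation p times 2 was 0.0536. That misses the threshold, and a biological difference between the sets was not tested.

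The astrocyte and Bergmann glia score was −1.98 in unmarked replicate 8, −1.53 in S-marked 10, −1.32 in unmarked 2, −1.21 in unmarked 3 and −0.79 in asterisk-marked 1, with a gap of 0.56 to the next array. Precursor scores on these 5 arrays were −1.05, −1.14, −1.08, −0.81 and −0.73, and oligodendrocyte scores −0.87, −0.15, −0.64, 0.02 and 0.08. Microglia scores on them were −0.41, −0.46, −0.15, −0.35 and −0.55. A varying share of all glia in the dissected piece stays open. Over all arrays r was over 0.3 for 2 of 2 other glial scores, as the test set beforehand asked, but both 95% intervals include 0, with oligodendrocytes at 0.43 (−0.07 to 0.70, rho = 0.15) and microglia at 0.34 (−0.01 to 0.67). Within the other 23 arrays, a division chosen after seeing the data, r was −0.04 (95% interval −0.45 to 0.39) and −0.02 (−0.43 to 0.54). RNA degradation and the RNA number division are argued against as the main source of the spread, since they shared 1.361% and 0.213% of the score's variance, with upper 95% bounds of 23.1% and 18.4%. With the quality index r was 0.12 over all arrays, where rho was −0.14. Without the 2 arrays farthest from the median index r was −0.37, so its sign and size rest on few arrays.

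Each of the 2 biosource codes named for 2 arrays was checked for 1 shared donor. Of 16 genes with separated expression levels, both pairs disagreed in 9, against a median of 4 over other pairs, but 9 of the 16 genes followed the astrocyte score and 1 followed PC1 (r of at least 0.5 in size). The bound set beforehand, which the count of 9 met as evidence against 1 donor, was wrong where the astrocyte score differs between pieces. That judgement, made after the count was seen, holds for the pair whose scores differed by 2.04, with 8 of its 9 disagreements in such genes, and is weaker for the other pair, whose arrays both lie among the 5 lowest and differed by 0.53, near the median of 0.49 over other pairs, with 7 of 9 in such genes. Over the 7 genes without the astrocyte relation, the pairs disagreed in 1 and 2 against a median of 3 over other pairs. Over all genes, deviations from the gene means correlated at −0.071 and −0.058 in these pairs, against a median of −0.051 over all pairs. That likeness is no closer than in other pairs, but both pairs lie across the 2 RNA number sets, which differ in many genes. Shared and separate donors therefore cannot be told apart.

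The heat shock score was 3.69 in S-marked replicate 5 and 2.56 in unmarked replicate 9. S-marked replicate 5 also had the highest RNA quality index, 2.99 against 0.71 to 1.61 elsewhere. Over all arrays the heat shock score had r = 0.73 with the index (permutation p = 0.0136, adjusted p = 0.109). Over the 26 arrays on the larger side of the gaps r was −0.09 (permutation p = 0.671, adjusted p = 0.891). The metallothionein and acute phase score was 2.23 in unmarked replicate 9 and 1.20 in S-marked replicate 3. The immediate early score was 1.52 in asterisk-marked replicate 1 and 1.04 in S-marked replicate 5.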
